A study of Drosophila melanogaster with 6 samples.

How the data were processed

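Chromatin was prepared from Kc167 cells grown in serum-free medium, fixed with 1% formaldehyde for 10 min and sonicated to fragments of 200 to 1000 bp, per the labels' protocols. After immunoprecipitation with 1 of 6 antibodies, libraries were amplified by PCR and selected for 200 to 300 bp. Reads were aligned with Bowtie 0.12.5, per the submitters' processing notes. Peak names in the deposited files carry the name of the peak caller MACS; its version, its settings, any input control and the genome build are not given in the sources used here. The authors deposited 1 list of peaks per sample, each peak with a start, an end and a score. The deposited files do not say what the score is. It was taken to be -10 times log10 of the p-value of the peak, as MACS writes it, because the lowest deposited scores were 50.0 to 50.4, which on that scale is a p-value of 1e-05. Many peaks stood at 3100 (57.9% of H3K27ac scores were at or above it). Scores were therefore used only within a list, to rank peaks and to compare the median scores of its peaks. The start and end columns hold positions in bp, another kind of value than a score, and in the deposited H3K27acS28ph list 2 starts lay below 0 at scaffold ends. No peaks within one list overlapped each other. Read counts and depth per library are not used here, because the lists give none, and differences in depth or in the efficiency of an antibody move both the number and the width of called peaks.

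Samples were grouped by the antibody in their labels, 1 library each, and no sample was left out. The scaffold names (2LHet, Uextra) are those of release 5 of the genome. The gene table at hand describes release 6, and positions were not converted between releases, so the planned comparisons with transcription start sites and with lists of genes, and the naming of genes beside peaks, were not analysed here. Scaffold lengths were taken as the largest peak end over the 6 lists.

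A peak counted as overlapping another list when it shared at least 1 bp with one of its peaks. For each of the 15 pairs, the number of overlapped peaks of the shorter list was compared with 10000 circular shifts of the other list within each scaffold, which keep peak widths and spacing, and p-values are two-sided permutation values. For site types 1000 shifts were drawn. Shares have 95% Wilson intervals, which cover counting error only; neighbouring peaks are not independent, so differences of shares have 95% intervals from a bootstrap of 10000 resamples over 1 Mb blocks (1000 resamples for median scores). Differences were called when the interval excluded 0. Adjusted p-values are Benjamini-Hochberg values over the 14 differences of shares. Densities on chromosome 4 were compared by exact binomial intervals, which treat peaks as independent, and with random windows of the same length on the large arms. All p-values describe positions within these libraries.

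The definitions of promoter-type and enhancer-type sites, the tests, the main alternatives and the rule for named regions were fixed before the data were examined. The comparison of JIL-1 differences between site types, 2 of the 14 differences, was added afterwards, as were the limit to the arms for the differences of shares and the settings with 3223 arm peaks. The rule names the 5 highest-scoring arm peaks of JIL-1, H3K9acS10ph and H3K27acS28ph, the 5 widest merged regions with all 6 lists, and the 5 widest enhancer-type sites with JIL-1 and both phosphoacetylated marks. Ties in score were broken by width. The alternatives were an overlap of 50% of the shorter peak, the upper 50% of each list by score, all lists cut to 5303 peaks, windows of 1000 bp around midpoints, shifts of at most 100 kb, other distances from H3K4me3 (0 and 2000 bp), the middle 50% of site widths, and subsets of chromosomes. Site types were defined anew from the altered lists, so the sites compared could differ between settings. The cut to 5303 peaks was made over all scaffolds. On the arms H3K27acS28ph, with at most 3223 peaks, stayed shorter than the other lists. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. The procedures were tested on simulated data: of 100 pairs of unrelated lists with the sizes and widths of the H3K27acS28ph and H3K9acS10ph arm peaks, 9 were called at the 0.05 threshold, and all 100 were called when 10% of one list was placed on the other, with a mean recovered excess of 9.29%. The 9 calls lie above the nominal rate. Positions in these lists were drawn at random, so the rate of false calls for peaks that cluster was not measured. For shares of 60% and 40% simulated at H3K4me3 sites and 700 H3K4me1 sites, 98 of 100 block bootstrap intervals held the true difference.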

Results

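The series mapped 5 modified forms of histone H3 and the histone kinase JIL-1 by chromatin immunoprecipitation and sequencing (ChIP-seq) in Kc167, a cell line derived from female Drosophila melanogaster late embryos. The antibodies recognised H3K4me3, a mark of active promoters, H3K4me1, a mark of enhancers and of the flanks of promoters, H3K27ac, a mark of active promoters and enhancers, JIL-1, a kinase that phosphorylates histone H3 in interphase chromatin, and 2 phosphoacetylated forms, H3K9acS10ph and H3K27acS28ph, in which an acetylated lysine lies next to a phosphorylated serine. There was 1 library per antibody and there were no replicates, so the intervals given here describe how precisely a share or ratio is known within these lists and not the variation between chromatin preparations. Each library was represented by the authors' list of called peaks, with 9491 peaks for H3K4me3, 9559 for H3K4me1, 5303 for H3K27ac, 12417 for JIL-1, 6918 for H3K9acS10ph and 5634 for H3K27acS28ph. Read depth behind the lists is unknown. Peaks differed in width, with medians from 1074 bp for JIL-1 to 2512 bp for H3K27ac, and on the chromosome arms they covered from 5.77 Mb for H3K27acS28ph to 26.3 Mb for H3K4me1. In 5 lists, between 98.5% (H3K27ac) and 99.7% (H3K4me1) of the peaks lay on the arms 2L, 2R, 3L, 3R, X and chromosome 4, against 57.2% of the H3K27acS28ph peaks, of which 2280 lay on the unplaced sequence collections U and Uextra.

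The first comparison asked whether JIL-1 and the phosphoacetylated marks occupied the same places as the promoter and enhancer marks. They did so well beyond chance placement in all 15 pairs of lists. On the chromosome arms, 84.2% of the 3223 H3K27acS28ph peaks overlapped an H3K9acS10ph peak (95% Wilson interval 82.9 to 85.5), 82.5% overlapped H3K4me1, 82.1% overlapped H3K27ac, 79.6% overlapped H3K4me3 and 77.4% overlapped JIL-1. H3K9acS10ph peaks on the arms overlapped H3K4me1 in 80.2% of cases, H3K4me3 in 74.2%, JIL-1 in 73.5% and H3K27ac in 69.9%. H3K27ac peaks on the arms overlapped H3K4me1 by at least 1 bp in 93.9% of cases (93.2 to 94.5). Overlap depended on peak width. When each peak was replaced by 1000 bp around its midpoint, the share over all scaffolds fell in every pair of lists. Overlap with H3K4me1 went from 92.8% to 55.1% for H3K27ac and from 79.9% to 46.8% for H3K9acS10ph. For H3K27acS28ph it went from 47.4% to 24.8% over H3K4me1 and from 48.7% to 33.7% over H3K9acS10ph. With JIL-1 reduced to its 3223 highest-scoring arm peaks, it overlapped 42.2% of the H3K27acS28ph arm peaks. JIL-1 had the most peaks of the 6 lists, and 25.6% of its arm peaks (3143 of 12295) lay outside H3K4me3, H3K4me1 and H3K27ac, compared with 7.33% of H3K9acS10ph and 11.1% of H3K27acS28ph arm peaks. These lists differ in length. Of all JIL-1 arm peaks 23.6% overlapped no other list, against 9.36% of the upper 10% by score. Over all scaffolds the observed counts were 2.22-fold (H3K9acS10ph over JIL-1) to 3.61-fold (H3K27acS28ph over H3K4me3) above the mean of 10000 circular shifts of one list within each chromosome. For example, 2744 of all 5634 H3K27acS28ph peaks overlapped H3K9acS10ph, against 788 in the shifts (95% of shifts between 727 and 854). Under the alternative settings the folds ran from 1.75 to 5.37. The two-sided permutation p was 0.0002 in every pair, the smallest the shifts can give. With the peaks on all other scaffolds included (2280 on U and Uextra and 131 on the assembled heterochromatin scaffolds), the share of H3K27acS28ph peaks over H3K9acS10ph was 48.7% in place of 84.2%, and the shares over the other lists fell alike.

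**Figure D1:**
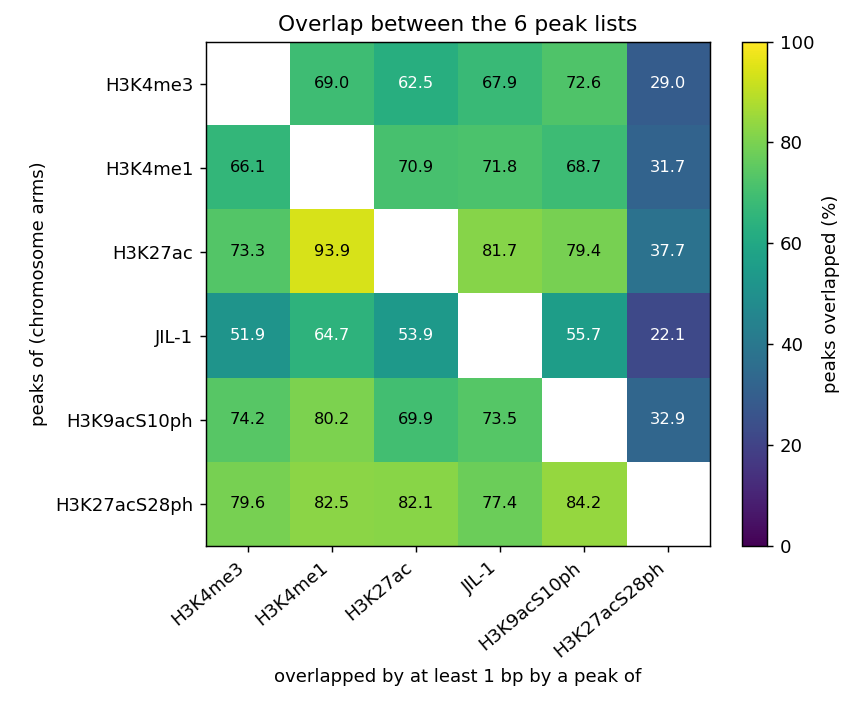
Share of the peaks of each list (rows, chromosome arms) overlapped by at least 1 bp by a peak of each other list (columns), in percent, with the colour scale running from 0 to 100%. H3K27acS28ph peaks are overlapped by every other list at 77.4% to 84.2%, whereas they overlap 22.1% of JIL-1 peaks to 37.7% of H3K27ac peaks.

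The second comparison set promoter-type against enhancer-type sites. Promoter-type sites were the 9491 H3K4me3 peaks, and enhancer-type sites were the 718 H3K4me1 peaks that overlapped H3K27ac and lay at least 500 bp from any H3K4me3 peak. JIL-1 was found at 67.7% of promoter-type sites (66.8 to 68.7) and at 62.4% of enhancer-type sites (58.8 to 65.9). H3K9acS10ph was found at 72.4% of promoter-type sites (71.5 to 73.3) and at 47.1% of enhancer-type sites (43.4 to 50.7). H3K27acS28ph was found at 29.1% of promoter-type sites (28.2 to 30.0) and at only 5.29% of enhancer-type sites (38 of 718, 3.88 to 7.18). The shifted lists gave 36.8% for JIL-1, 29.7% for H3K9acS10ph and 12.8% for H3K27acS28ph at enhancer-type sites, so that the full JIL-1 and H3K9acS10ph lists lay above chance placement there and H3K27acS28ph below it. These shares depended on the length of the lists. Reduced to as many arm peaks as H3K27acS28ph (3223), JIL-1 was found at 30.2% of promoter-type and 24.5% of enhancer-type sites on the arms, and H3K9acS10ph at 48.5% and 10.1%, against 29.0% and 5.33% for H3K27acS28ph. The enhancer-type class leaves out the surroundings of H3K4me3 peaks, and 79.6% of the H3K27acS28ph peaks on the arms, or 46.0% of the whole list, overlapped H3K4me3. The shifts were not held to this limit, so the H3K27acS28ph share below them follows at least in part from the definition. All 3 marks were present together at 2365 promoter-type sites (24.9%) and at 20 enhancer-type sites (2.79%). None of the 3 was present at 16.4% of promoter-type and 24.8% of enhancer-type sites.

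Promoter-type exceeded enhancer-type shares by 25.3 percentage points for H3K9acS10ph (95% interval of a block bootstrap over 1 Mb blocks 20.2 to 30.4), by 23.8 points for H3K27acS28ph (21.3 to 26.1) and by 5.34 points for JIL-1 (1.13 to 9.70). Benjamini-Hochberg adjusted bootstrap p-values over the 14 differences tested were 0.0003 for both phosphoacetylated marks and 0.0151 for JIL-1. The JIL-1 difference was 16.2 points when every peak was replaced by 1000 bp around its midpoint and 15.8 points with lists of equal length, and its interval included 0 (4.32 points, -0.125 to 8.97) when enhancer-type sites had to lie 2000 bp from H3K4me3. Site types were defined anew in each setting, so these are not the same sites. There were 898 enhancer-type sites with windows and 835 with lists of equal length, against 718 in the main setting. With lists of equal length the H3K27acS28ph difference was 36.3 points, and with H3K9acS10ph reduced to 3223 arm peaks its difference was 38.4 points. The equal length held over all scaffolds, and on the arms the H3K27acS28ph list stayed shorter than the others. Enhancer-type sites were wider than promoter-type sites, with median widths of 3322 and 1241 bp.

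**Figure D2:**
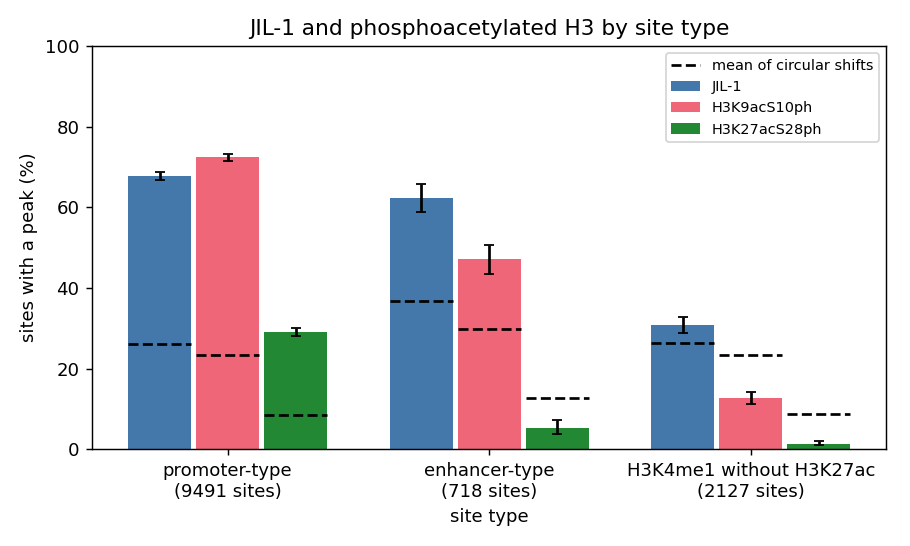
Percentage of sites of each type (horizontal axis) that carry a peak of JIL-1, H3K9acS10ph or H3K27acS28ph, with 95% Wilson intervals as error bars and the mean of 1000 circular shifts as dashed lines. H3K27acS28ph falls from 29.1% at promoter-type sites to 5.29% at enhancer-type sites, while JIL-1 is at 67.7% and 62.4%.

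The third comparison separated H3K4me1 sites away from H3K4me3 by whether they carried H3K27ac, the acetylation that distinguishes active enhancers. JIL-1 and both phosphoacetylated marks were more frequent where H3K27ac was present. JIL-1 was found at 62.4% of the 718 sites with H3K27ac and at 30.7% of the 2127 sites without it, a difference of 31.6 points (26.9 to 36.2). H3K9acS10ph was found at 47.1% and 12.6%, a difference of 34.5 points (29.4 to 39.5). H3K27acS28ph was found at 5.29% and 1.36%, a difference of 3.93 points (2.08 to 5.90). All 3 differences had an adjusted bootstrap p of 0.0003. At sites without H3K27ac, H3K9acS10ph and H3K27acS28ph lay below the shifted lists, which gave 23.4% and 8.68%, while JIL-1 was slightly above its 26.4%. These sites leave out H3K27ac and the surroundings of H3K4me3. On the arms, 74.2% of H3K9acS10ph and 79.6% of H3K27acS28ph peaks overlapped H3K4me3. The shifts were not held to this limit, so shares below them follow at least in part from the definition. Sites with H3K27ac were also wider (3322 against 1345 bp), and with equal 1000 bp windows the differences were 15.5 points for JIL-1, 21.4 for H3K9acS10ph and 3.68 for H3K27acS28ph, all with intervals above 0. The windows also changed the sites, to 898 with and 3501 without H3K27ac. With JIL-1 and H3K9acS10ph reduced to their 3223 highest-scoring arm peaks, the differences were 14.4 points for JIL-1 and 9.25 for H3K9acS10ph, with JIL-1 at 14.6 points with lists of equal length, and the H3K27acS28ph difference was 6.94 points in the upper 50% of each list by score.

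The fourth comparison asked whether the phosphoacetylated marks lay where the kinase lay. At promoter-type sites both marks were more frequent at sites with JIL-1. H3K9acS10ph was present at 83.9% of the 6429 promoter-type sites with JIL-1 (83.0 to 84.8) and at 48.1% of the 3062 without it (46.3 to 49.9). H3K27acS28ph was present at 38.3% (37.1 to 39.5) and 9.70% (8.70 to 10.8). At enhancer-type sites H3K9acS10ph was present at 55.8% of the 448 sites with JIL-1 (51.2 to 60.3) and at 32.6% of the 270 without it (27.3 to 38.4), whereas H3K27acS28ph was present at 5.58% (3.81 to 8.11) and 4.81% (2.83 to 8.06). H3K9acS10ph was also called without JIL-1 at 1473 promoter-type and 88 enhancer-type sites, and JIL-1 was called without either phosphoacetylated mark at 937 promoter-type and 193 enhancer-type sites. Overlap with JIL-1 was not particular to the phosphoacetylated marks. On the arms JIL-1 overlapped 73.5% of H3K9acS10ph and 77.4% of H3K27acS28ph peaks. It also overlapped 81.7% of H3K27ac, 71.8% of H3K4me1 and 67.9% of H3K4me3 peaks there.

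The differences between sites with and without JIL-1 were 35.8 points for H3K9acS10ph (33.6 to 38.1) and 28.6 points for H3K27acS28ph (26.7 to 30.4) at promoter-type sites, and 23.2 points for H3K9acS10ph at enhancer-type sites (15 to 31.0), each with an adjusted bootstrap p of 0.0003. The H3K27acS28ph difference at enhancer-type sites was 0.766 points (-3.12 to 4.41), with an adjusted p of 0.663. It was 3.18 points (-0.116 to 6.67) with 1000 bp windows, 2.75 points (-0.314 to 5.86) with an overlap of 50% of the shorter peak and 2.58 points (-0.449 to 5.54) with lists of equal length, so a difference of up to 6.67 points was not excluded under these settings. The lists of equal length were equal over all scaffolds and not on the arms. With lists of equal length the H3K9acS10ph difference at promoter-type sites was 14.3 points, and with the H3K9acS10ph list alone reduced to the 3223 strongest arm peaks its difference at enhancer-type sites was 6.51 points (2.44 to 10.7), and 5.55 points (-0.685 to 12.1) when JIL-1 was reduced alike. In the upper 50% of each list by score the differences at promoter-type sites were 23.5 points for H3K9acS10ph and 15.8 points for H3K27acS28ph. In the middle 50% of site widths they were 25.9 and 19.3 points. The H3K9acS10ph difference at enhancer-type sites was then 16.5 points (4.78 to 28.1).

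**Figure D3:**
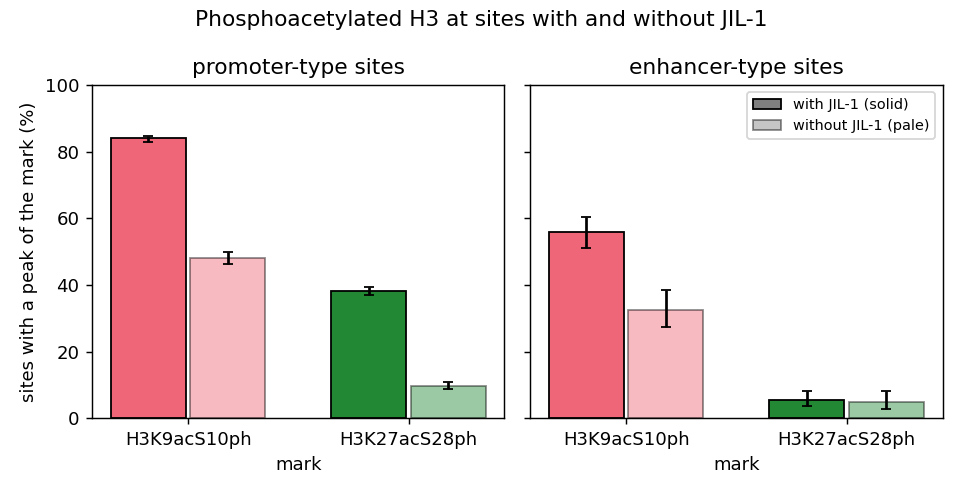
Percentage of promoter-type (left) and enhancer-type (right) sites that carry H3K9acS10ph or H3K27acS28ph, split by the presence (solid) or absence (pale) of a JIL-1 peak, with 95% Wilson intervals. The bars differ except for H3K27acS28ph at enhancer-type sites, at 5.58% and 4.81%.

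The fifth comparison set the 2 phosphoacetylated marks against each other. Of the 2758 promoter-type sites with H3K27acS28ph, 2629 also carried H3K9acS10ph (95.3%, 94.5 to 96.0), against 72.4% of all promoter-type sites. A further 4240 promoter-type sites had H3K9acS10ph without H3K27acS28ph, and 129 had H3K27acS28ph alone of the 2. At enhancer-type sites 29 of 38 sites with H3K27acS28ph carried H3K9acS10ph (76.3%, 60.8 to 87.0), against 47.1% of all enhancer-type sites, while 309 sites had H3K9acS10ph without H3K27acS28ph. The share with H3K9acS10ph exceeded that with H3K27acS28ph by 43.3 points at promoter-type sites (41.9 to 44.7) and by 41.8 points at enhancer-type sites (36.2 to 47.5), both with an adjusted bootstrap p of 0.0003. The H3K9acS10ph list holds 6873 arm peaks and the H3K27acS28ph list 3223. When H3K9acS10ph was reduced to its 3223 highest-scoring arm peaks, the differences were 19.5 points at promoter-type (17.9 to 21.1) and 4.77 points at enhancer-type sites (2.05 to 7.55), and with 1000 bp windows they were 28 and 27.1 points. On the arms, H3K9acS10ph overlapped 84.2% of H3K27acS28ph peaks, and 72.6% when reduced to 3223 peaks.

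The sixth comparison concerned the X chromosome, on which JIL-1 is known to be enriched in male flies. In these female cells JIL-1 peaks were as dense on X as on the autosomal arms within error, at 104 and 102 peaks per Mb, a ratio of 1.01 (0.905 to 1.12). The ratio was 1.01 for H3K9acS10ph (0.859 to 1.19), 1.11 for H3K27acS28ph (0.943 to 1.29), 0.951 for H3K4me3 (0.788 to 1.13), 1.02 for H3K4me1 (0.875 to 1.18) and 0.988 for H3K27ac (0.843 to 1.14). No interval excluded 1. Numbers of peaks do not measure how much JIL-1 is bound at each of them, so these ratios are not a direct test of such enrichment. The JIL-1 ratio was 1.11 (0.962 to 1.27) in the upper 50% of the list by score and 1.11 (0.956 to 1.28) with lists of equal length.

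**Figure D4:**
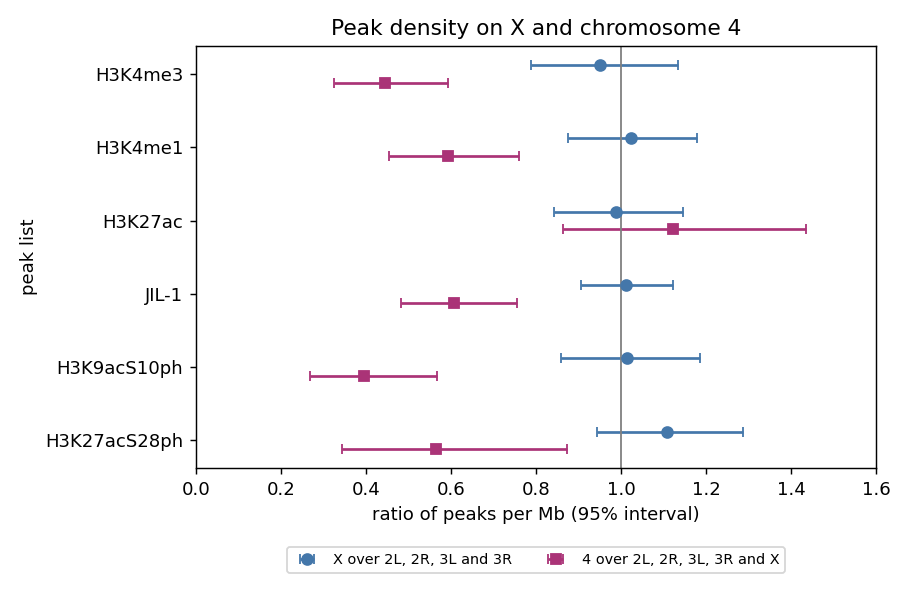
Ratio of peaks per Mb on X over the autosomal arms (circles, 95% block bootstrap intervals) and on chromosome 4 over the large arms (squares, 95% exact intervals) for each peak list. The X ratios lie between 0.951 and 1.11, and on chromosome 4 only H3K27ac has an interval that includes 1, where the exact intervals treat peaks as independent.

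Peaks that coincided with other marks were stronger by the authors' peak score, taken as a measure of significance and used only within one list. On the arms, H3K9acS10ph peaks with 4 or 5 of the other marks had a median score of 1064 (3750 peaks), against 84.3 for those with 0 or 1 (1105 peaks), a difference of 980 (block bootstrap interval 907 to 1046). The medians were 353 and 87.3 for JIL-1, a difference of 266 (246 to 278), and 156 and 107 for H3K27acS28ph, a difference of 49.2 (31.9 to 64.6). For H3K4me3 and H3K27ac the median of peaks with 4 or 5 other marks stood at 3100, a value at which scores pile up, so their differences of 3018 and 2831 are not full measures. The H3K4me1 medians were 1804 and 310. In all lists but H3K27acS28ph, peaks with 4 or 5 other marks were also wider than those with 0 or 1.

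Merging the 6 lists gave 14885 regions, 12336 of them on the arms. All 6 lists were present in 1562 regions on the arms (12.7%), and 1065 held all but H3K27acS28ph. JIL-1 alone made up 2907 regions on the arms (23.6%), H3K4me1 alone 1407 and H3K4me3 alone 1167. Coordinates are given 1-based with start and end included, on scaffolds whose names are those of release 5 of the fly genome. The widest region with all 6 lists lay on 3L from 3393148 to 3468062 (74.9 kb, with 8 JIL-1, 3 H3K9acS10ph and 3 H3K27acS28ph peaks). The next lay on 2R from 7476121 to 7540696, on 3R from 18992490 to 19050517, on X from 10654186 to 10705428 and on X from 12604553 to 12654107. The widest enhancer-type sites with JIL-1 and both phosphoacetylated marks lay on 3R from 17403760 to 17434923 (31.2 kb), on 3R from 12878065 to 12896082, on X from 7590654 to 7605637, on 3L from 8831902 to 8845705 and on 3R from 21943012 to 21955703.

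The 5 highest-scoring arm peaks of H3K27acS28ph lay on 3R from 25870751 to 25873623, on 2R from 17030021 to 17035572, on X from 5626050 to 5630085, on 3L from 22066892 to 22070374 and on 2R from 12473127 to 12474657. Those of H3K9acS10ph lay on 3R from 6086479 to 6090973, on 2R from 10156161 to 10158614, on 2L from 17409478 to 17412365, on X from 21882112 to 21886405 and on X from 16776532 to 16781988. Each of these peaks overlapped all 5 other lists. The 5 highest-scoring JIL-1 arm peaks differed in this respect. The peak on X from 2030292 to 2033072 overlapped all 5 other lists, and that on X from 5801642 to 5802703 overlapped 4. The highest-scoring, on X from 18264325 to 18266236, overlapped H3K4me3, H3K4me1 and H3K27ac and neither phosphoacetylated mark. The peak on 3R from 12528160 to 12529413 overlapped H3K4me1 alone, and that on 2R from 10321302 to 10322487 overlapped no other list. Scores pile up at 3100, and the order of scores at or above that value may not follow strength. In the JIL-1 list 167 peaks stood at or above it, so the 5 named here need not be its strongest. The same limit applies to the peaks named for the phosphoacetylated marks.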

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

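The comparison of the JIL-1 differences between site types, the list reduction applied to it and the direct comparison of the 2 marks at enhancer-type sites were chosen after the data were seen, and the test of the JIL-1 difference at enhancer-type sites was revised after a first result; the tests of the ratio of shares were set before their results.

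The difference in H3K27acS28ph between sites with and without JIL-1 was larger at promoter-type than at enhancer-type sites by 27.8 points (23.7 to 32.2), and the same contrast for H3K9acS10ph was 12.6 points (4.31 to 21.3). Each was a tested difference between site types under one contrast. Contrasts in points depend on how frequent a mark is at each site type. H3K27acS28ph was at 38 of 718 enhancer-type sites (5.29%), too few for a difference there near the 28.6 points at promoter-type sites. A positive H3K27acS28ph contrast therefore followed from the low share. H3K9acS10ph was also less frequent at enhancer-type sites (47.1% against 72.4%). The H3K27acS28ph contrast had an interval above 0 in each of the alternatives tried, the lowest value being 15.3 points in the upper 50% of each list, whereas the H3K9acS10ph contrast did not. The H3K27acS28ph share at enhancer-type sites stayed low in the alternatives, at most 7.45% in the upper 50% of each list. This left little room for the sign of its contrast to change.

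In the same comparison, the enhancer-type share divided by the promoter-type share was 0.650 for H3K9acS10ph (0.581 to 0.721) and 0.182 for H3K27acS28ph (0.12 to 0.250), which at first sight sets the 2 marks apart. With 1000 bp windows, which also changed the enhancer-type sites (898 in place of 718), the ratios still differed by 0.367 (0.262 to 0.470). For the sites so defined, this argues against wider H3K9acS10ph peaks as the whole reason for the gap. The number of called peaks may account for this gap: with H3K9acS10ph reduced to as many arm peaks as H3K27acS28ph, its ratio was 0.208 and the difference of the ratios was 0.0243 (-0.0502 to 0.0968). The reduced H3K9acS10ph list also had a JIL-1 difference larger at promoter-type than at enhancer-type sites, by 38.2 points (33.6 to 42.9). It was at only 10.1% of enhancer-type sites, too few for a difference there near the 44.7 points at promoter-type sites. A positive contrast thus followed from the low share, so this test cannot decide whether list length accounts for the smaller effect at enhancer-type sites. Whether list length also accounts for the lack of a called JIL-1 difference in H3K27acS28ph at enhancer-type sites is undecided: the first test, with JIL-1 and H3K9acS10ph both reduced, left H3K9acS10ph a difference of 5.55 points (-0.685 to 12.1), and the revised one, with H3K9acS10ph alone reduced, 6.51 points (2.44 to 10.7). The H3K9acS10ph difference exceeded that of H3K27acS28ph by 5.04 points (-1.23 to 11.6) in the first and by 5.81 points (0.787 to 11.0) in the second, and a different kinase or a less efficient antibody was not tested.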

How the results depend on the processing

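The limit to the chromosome arms for the differences of shares, the settings that reduce lists to the 3223 arm peaks of H3K27acS28ph, and every alternative for the contrast of JIL-1 differences between site types, were chosen after seeing the data. All 105 alternative folds for the 15 pairs of lists stayed above 1 and past the threshold; they ran from 1.75 to 2.61 with shifts of at most 100 kb, which keep peaks in their neighbourhood, and up to 5.37 in the upper 50% of each list. All 18 alternative X ratios (0.925 to 1.21) kept intervals that included 1, and 3 of them crossed to the other side of 1 when covered bp replaced peaks: JIL-1 at 0.962, H3K9acS10ph at 0.943 and H3K27ac at 1.02. Of 119 alternative values of the 14 differences of shares, 112 kept their direction and side of the threshold. Some of these values repeat each other, because a setting that reduces a list leaves differences that do not use that list unchanged. The H3K27acS28ph difference by JIL-1 at enhancer-type sites, not past the threshold in the main or any alternative setting, turned to -0.819 (-4.96 to 2.95) in the middle 50% of site widths. The JIL-1 difference between promoter-type and enhancer-type sites was 4.32 points and no longer past the threshold at 2000 bp from H3K4me3, where fewer sites (533) remained. The H3K9acS10ph difference by JIL-1 at enhancer-type sites was 5.55 points (-0.685 to 12.1) when JIL-1 and H3K9acS10ph were both reduced to 3223 arm peaks. The contrast of H3K9acS10ph JIL-1 differences between site types was 5.45 points with an overlap of 50% of the shorter peak, 0.342 in the upper 50% of each list and 9.38 in the middle 50% of site widths, with intervals that included 0, and it reversed to -4.01 (-11.8 to 3.60) with lists of equal length; the cause was not tested. The overlap and width settings cannot change the number of peaks per Mb and were not run for the X ratio. Median scores have no alternative settings. The restriction by distance from annotated starts was not run, as no annotation of the same genome release was used. No paired analysis was possible because each antibody has 1 library, and no library could be left out. Unknown read depth limits every statement about the absence of a peak.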

Other observations

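The tests of the unplaced sequences, of mappability on chromosome 4 and of the overlaps of its H3K27ac peaks were chosen after the data were seen, and the criterion for mappability was revised once. The test of the reduced H3K27ac list was likewise written after the data were seen, and the chromosome 4 tests were narrowed to H3K9acS10ph afterwards.

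On chromosome 4, the small chromosome of the fly that is largely heterochromatic, the balance of marks differed from the large arms. H3K27ac peaks were about as dense there as on the large arms, at 48.6 and 43.4 per Mb, a ratio of 1.12 (exact 95% interval 0.863 to 1.43). The ratio was 0.396 for H3K9acS10ph (0.267 to 0.566), 0.444 for H3K4me3 (0.325 to 0.593), 0.565 for H3K27acS28ph (0.344 to 0.873), 0.592 for H3K4me1 (0.454 to 0.760) and 0.607 for JIL-1 (0.482 to 0.754). The 64 H3K27ac peaks on chromosome 4 overlapped each of the 5 other lists less often than the 5158 on the large arms. The shares were 48.4% against 94.4% for H3K4me1, 43.8% against 79.8% for H3K9acS10ph, 53.1% against 73.6% for H3K4me3, 18.8% against 37.9% for H3K27acS28ph and 65.6% against 81.9% for JIL-1. Benjamini-Hochberg adjusted p-values of Fisher's exact test (two-sided), which treats peaks as independent, were at most 0.0018. These exact intervals treat peaks as independent, although peaks cluster. Of 1000 random windows of the same length on the large arms, 15 held as few H3K9acS10ph peaks as chromosome 4, 26 as few H3K4me3, 47 as few JIL-1, 61 as few H3K4me1, 129 as few H3K27acS28ph and 645 as few H3K27ac peaks.

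JIL-1 was often called where no other mark was. On the arms, 2907 of 12295 JIL-1 peaks (23.6%, 22.9 to 24.4) overlapped none of the 5 histone lists. Their median score was 79.5, against 217 for the rest, and their median width was 742 bp, against 1196 bp. Among the strongest 10% of JIL-1 arm peaks, 115 of 1229 (9.36%, 7.85 to 11.1) also lay apart from the histone lists. The longest stretch of an arm without a peak of any list lay on 2L from 4466156 to 4659774 (194 kb), and 17 stretches exceeded 100 kb, where the median distance between merged regions was 2.43 kb.

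The scarcity of H3K9acS10ph peaks on chromosome 4 is a hypothesis drawn from these lists. The H3K27ac ratio of 1.12 (0.863 to 1.43) lies above the H3K9acS10ph interval of 0.267 to 0.566. If sequence that takes few unique reads thinned all lists alike, this would argue against it as the whole cause. Strong peaks could be spared, however, and 57.9% of H3K27ac scores stood at or above 3100, so this comparison cannot decide. The H3K27ac list reduced to 3223 arm peaks had a ratio of 1.19 (0.859 to 1.62), which has no bearing on H3K9acS10ph, whose list of 6873 arm peaks is longer than the 5222 of H3K27ac. No biological explanation was tested.

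The H3K27acS28ph list stood apart from the other 5 in having 2280 of its 5634 peaks (40.5%, 39.2 to 41.8) on U and Uextra, collections of unplaced and low-quality sequence, where the other lists had at most 21 peaks. Weak calls near the threshold are argued against, since the share was 43.7% (41.9 to 45.5) in the upper 50% of the list by score and the median score was 172 there against 141 on the arms. Repeated sequence that collects reads when an antibody enriches little, and heterochromatin that carries the mark, cannot be told apart: both predict the excess also seen on the assembled heterochromatin scaffolds, which held 3.91% of placed H3K27acS28ph peaks (3.30 to 4.62), against at most 1.49% (1.20 to 1.85) in another list, and no input library was used here. Foreign DNA matched by Uextra was not tested.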
